A study of Homo sapiens with 28 samples.

How the data were processed

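RNA sequencing of polyadenylated RNA from AN3CA cells was available for 28 libraries: 4 of an empty vector and 2 of each of 12 constructs of ARID1A or ARID1B. Per the submitters' processing notes, reads were processed with bcl2fastq, STAR 2.5.2b and Bowtie2 2.29 on genome build hg19, with neither the role of each tool nor the gene annotation stated. The deposited files hold raw counts of reads per gene for 26346 gene symbols in the 4-column layout that STAR writes: reads counted without regard to strand, reads on the strand of the gene and reads on the opposite strand. No normalization was applied by the authors to these deposited counts. The column of reads on the opposite strand was used, since it held 84.5 to 98.6% of stranded gene reads, and the unstranded column served as an alternative. The first 4 lines of each file, totals of reads that name no gene, were kept out of the tests.

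Depth was 16.6 to 27.9 M reads on genes per library, so a gene at 1 count per M reads (CPM) rests on about 17 to 28 reads per library. Genes were kept by filterByExpr of edgeR by group, which left 14220 genes. Libraries were scaled by TMM factors, and CPM values use these. One edgeR quasi-likelihood fit over all 28 libraries and 13 groups, with no other covariate, gave every contrast: 12 of a construct against the empty vector and 11 between constructs. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in the two-sided quasi-likelihood F test, and adjusted p values of genes are from this test. Standard errors of log2 fold changes are the size of the log2 fold change over the square root of its F statistic. For large changes of genes near 0 in a group they can fall below the counting error. Counts at least 2-fold require a call and a log2 fold change of at least 1 either way. Where a group held no read of a gene, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is the ratio of normalized counts with a 95% counting interval.

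A total of 35 gene lists of 39 written beforehand had at least 3 tested members, and each was tested with camera of limma on the edgeR fit with a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast. The test was repeated with a correlation estimated per list. Members were also counted with p adjusted over the list alone. Of 956 list entries 943 were found, and the 13 others are mitochondrially encoded. Response medians are over the genes called in WT against the empty vector. They were recomputed with genes chosen against a pair of empty vector libraries and folds taken against the other. Simulation of 20 sets of libraries, without an effect and without the split of the empty vector into pairs, gave a level for shared controls.

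Genes were named by a rule written beforehand. For WT against the empty vector it took the 10 largest rises and the 10 largest falls, and for other contrasts the 3 largest each way, among called genes with an average log2 CPM of at least 1, every library beyond every reference library, and symbols other than LOC, LINC, MIR, SNOR, antisense or dotted names. Up to 4 called members with the smallest p were added per list, with ARID1A, ARID1B, DDX4 and the subunits of the BAF complex. Genes given for the empty vector pairs, for contrasts within set 3 and in the figures were picked from these after their values were seen. Of the genes picked by the rule, 1 is not reported here.

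The 3 strand sets were found in the data. A fit with the empty vector pairs as separate groups set each construct of sets 1 and 2 against its own pair, and contrasts across sets were differences of such differences. Other alternatives were DESeq2 (Wald test), RLE size factors, no filter on low counts, an average log2 CPM of at least 1, a replicate block, fits of only the groups compared, each empty vector pair as the only control and leaving out each library. The fit was checked on simulated data with seeded changes of 1.5 to 8-fold. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. GC content and transcript length came from an annotation of another build and were matched by symbol. No coordinates were used. Raw reads, protein and chromatin data of the series were not analysed here.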

Results

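The libraries measured polyadenylated RNA of AN3CA cells, a human endometrial carcinoma line, that carried an empty vector or a construct of ARID1A or ARID1B. Both proteins are alternative subunits of the canonical BAF complex, a chromatin remodeller, and both hold an ARID DNA-binding domain and long disordered regions. The empty vector had 4 libraries and each of the 12 constructs had 2, which gave 28 libraries in 13 groups. The 7 ARID1A constructs were wild-type (WT), the truncations CBR and delIDR1, the ARID-domain mutant DBDmut, a hybrid with the disordered region of the germline helicase DDX4, a construct called AQG scramble (AQGscram) and a construct called 42YS. Labels of the last write its letters and number in more than 1 order, which leaves open whether 42 tyrosines or tyrosine 42 became serine. The 5 ARID1B constructs were WT, M2, A457_G461del, Block13del and Block9del, the last 4 being deletions per the labels. Each library held 16.6 to 27.9 M reads on genes (median 22.0 M), and 14220 genes were tested. Errors after log2 fold changes are standard errors and errors after counts per M reads on genes (CPM) are standard deviations, with n = 2 per construct and n = 4 for the empty vector. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

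Empty vector replicates 3 and 4 differed from empty vector replicates 1 and 2 in RNA of growth and stress genes, named after their values were seen. The cell cycle inhibitor gene CDKN1A was lower in replicates 3 and 4 (10.4 ± 0.964 against 85.0 ± 0.958 CPM, n = 2 each, log2 fold change -3.03 ± 0.077, adjusted p = 1.26e-20). So were the stress cytokine gene GDF15 (-3.13 ± 0.082) and the immediate early gene EGR1 (-2.23 ± 0.065). The replication helicase gene MCM5 (0.71 ± 0.053) and the sterol synthesis gene MSMO1 (1.11 ± 0.059) were higher. Of the p53 targets, 1 up, 22 down and 0 not called of 23, 1 up and 22 down adjusted over the list alone, camera adjusted p = 3.77e-15. The immediate early genes fell throughout (0 up, 21 down and 0 not called of 21, 0 up and 21 down adjusted over the list alone, camera adjusted p = 2.68e-17). Cell cycle genes rose (39 up, 0 down and 1 not called of 40, 39 up and 0 down adjusted over the list alone, camera adjusted p = 1.6e-27), and cholesterol genes did too (21 up, 0 down and 2 not called of 23, 21 up and 0 down adjusted over the list alone, camera adjusted p = 1.01e-29). Cytosolic ribosomal protein genes were higher by count (57 up, 0 down and 1 not called of 58, 57 up and 0 down adjusted over the list alone, camera adjusted p = 2.93e-26 and adjusted p = 0.134 with an estimated correlation). Between the pairs 4089 genes rose and 4226 fell, 508 and 951 of them at least 2-fold.

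The share of gene reads on the strand opposite to the gene divided the libraries into 3 sets that the labels do not give. It was 84.5 to 87.8% in ARID1A WT, CBR, delIDR1, DBDmut and empty vector replicates 1 and 2 (set 1). It was 98.1 to 98.6% in the ARID1A DDX4 hybrid, ARID1B WT, M2 and empty vector replicates 3 and 4 (set 2). The ARID1A constructs AQGscram and 42YS and the ARID1B deletions A457_G461del, Block13del and Block9del had 96.7 to 97.9% (set 3) and no empty vector library. Each construct of sets 1 and 2 was therefore also tested against the empty vector pair of its own set (own pair), a choice made after the data were seen. Genes picked by the naming rule whose difference shrank with strand ignored were ATP6V1C2 (8.50 in ARID1A WT against ARID1B WT, -0.02 with strand ignored), P2RX5-TAX1BP3 (-6.67 in ARID1B WT against empty vector, -0.31 with strand ignored) and SNX22 (-6.88 in M2 against empty vector, 0.03 with strand ignored). ZACN and BMP6, higher in ARID1A WT than in ARID1B WT, had 0 reads and 1 read in ARID1B WT and as many in its own pair, too few to compare the own-pair responses (adjusted p = 1 and adjusted p = 0.909).

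RNA of the expressed genes was raised in most, not all, construct groups. ARID1A stood at 289 ± 12.5 CPM with the empty vector and at 733 ± 43.8 with WT (2.54-fold). It reached 1017 ± 26.1 with CBR, 665 ± 40.6 with DBDmut, 589 ± 11.2 with delIDR1 and 523 ± 8.10 with the DDX4 hybrid. It was 374 ± 1.32 with 42YS (1.30-fold) and 247 ± 52.6 with AQGscram (0.856-fold, log2 fold change -0.22 ± 0.086, adjusted p = 0.0645). The difference with AQGscram passed the test against either empty vector pair alone (-0.20 and -0.24). ARID1B stood at 98.0 ± 6.54 CPM with the empty vector, 3597 ± 225 with WT (36.7-fold) and 4250 ± 96.2 with M2. It was 2236 ± 32.9 with A457_G461del, 883 ± 7.14 with Block13del and 344 ± 0.277 with Block9del (3.50-fold). DDX4 was read at 46.0 ± 0.626 CPM in the hybrid and at 0.190 CPM or less in every other group. ARID1B RNA fell with ARID1A WT (0.685-fold, -0.55 ± 0.08, adjusted p = 1.46e-05) and ARID1A RNA fell with ARID1B WT (0.742-fold, -0.43 ± 0.087, adjusted p = 0.000559). ARID1B stood at 0.716-fold with CBR, 0.739 with DBDmut, 0.687 with delIDR1, 0.671 with AQGscram and 0.717 with 42YS. With the DDX4 hybrid it stood at 1.02-fold, so ARID1B RNA did not follow the level of ARID1A RNA. Reads do not tell the construct from the cell's own transcript, and protein was not analysed here. A truncated, hybrid or altered sequence may also give fewer ARID1A or ARID1B reads per transcript than WT.

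**Figure D1:**
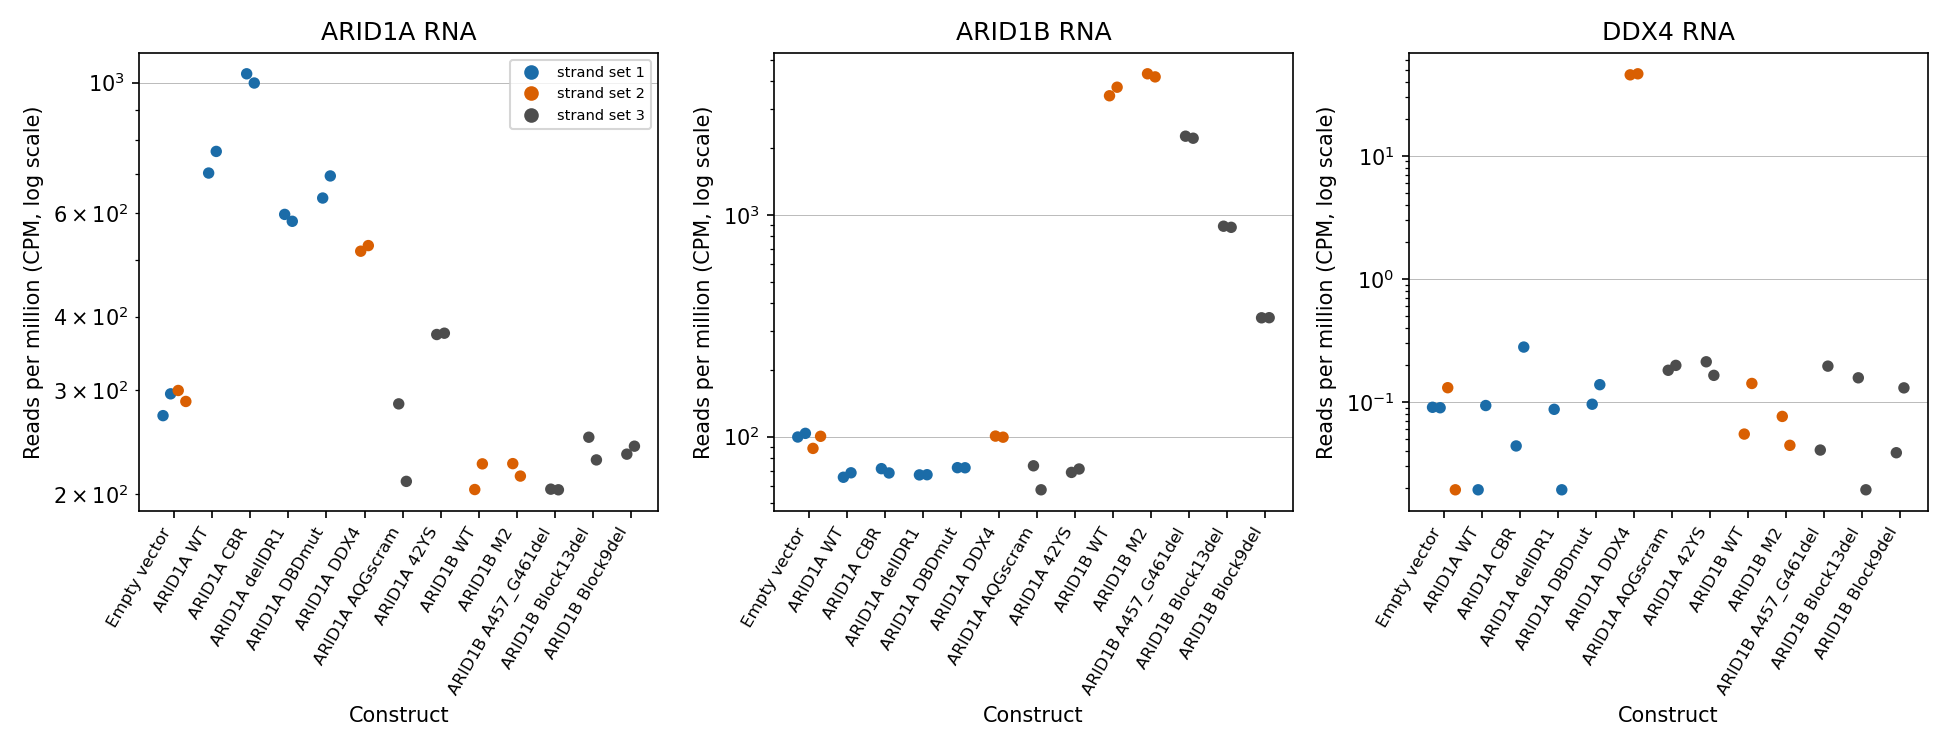
ARID1A, ARID1B and DDX4 CPM in each library (points) of the 13 groups, on a log axis with 0 drawn at the lower edge. ARID1B averaged 98.0 CPM with the empty vector, and group means spanned 65.8 CPM with AQGscram to 4250 CPM with M2.

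ARID1A WT turned on genes of the extracellular matrix and cell adhesion. The gelatinase gene MMP2 rose from 0.114 ± 0.0534 to 87.4 ± 1.86 CPM (log2 fold change 9.49 ± 0.185, adjusted p = 1.44e-18). The laminin gene LAMB1 rose from 8.09 ± 0.338 to 328 ± 4.08 CPM (5.34 ± 0.067, adjusted p = 1.7e-21) and the fibrillar collagen gene COL1A1 from 0.753 ± 0.332 to 89.3 ± 1.27 CPM (6.91 ± 0.159, adjusted p = 1.24e-17). RUNX2, a skeletal transcription factor gene, had no read with the empty vector and rose at least 447-fold to 17.1 ± 2.13 CPM. Without an empty vector read, the calcium channel subunit gene CACNG4 rose at least 340-fold, the neuronal microtubule gene DCX at least 319-fold and the guidance gene SEMA5B at least 135-fold. Other large rises were those of COL16A1 (3790 times, counting interval 680 to 150000), the hyaluronan receptor gene CD44 (747 times, 133 to 29600) and VSTM2L (725 times, 200 to 6000). C15orf52 (8.88 ± 0.232) and the lipid flippase gene ATP8B1 (8.67 ± 0.199) rose as well. Such intervals cover counting error only. The largest falls were of the cancer-testis genes MAGEC2 (-4.63 ± 0.588, adjusted p = 2.39e-06) and MAGEC1 (-4.32 ± 0.51), the prolactin receptor gene PRLR (-4.54 ± 0.502) and the signalling adaptor gene GRB10 (-3.39 ± 0.289). They were followed by the retinoic acid synthesis gene ALDH1A2 (-3.27 ± 0.255), CLGN (-2.92 ± 0.612), LAMP3 (-2.79 ± 0.567), INHBE (-2.51 ± 0.372), AKNA (-2.43 ± 0.227) and KCNG1 (-2.40 ± 0.462).

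Gene lists put numbers on this change with ARID1A WT. Matrix glycoprotein and remodelling genes rose (22 up, 3 down and 5 not called of 30, 22 up and 3 down adjusted over the list alone, camera adjusted p = 1.19e-25). So did collagens (19 up, 0 down and 4 not called of 23, 19 up and 0 down adjusted over the list alone, camera adjusted p = 2.11e-19) and mesenchymal markers (9 up, 1 down and 2 not called of 12, 9 up and 1 down adjusted over the list alone, camera adjusted p = 4.7e-20). Integrins rose alike (12 up, 0 down and 3 not called of 15, 12 up and 0 down adjusted over the list alone, camera adjusted p = 4.82e-13). TEAD/YAP targets rose too (18 up, 1 down and 2 not called of 21, 18 up and 1 down adjusted over the list alone, camera adjusted p = 8.03e-13), among them AXL (3.87 ± 0.099) and ANKRD1 (5.52 ± 0.165). Epithelial markers rose (9 up, 1 down and 7 not called of 17, 9 up and 1 down adjusted over the list alone, camera adjusted p = 2.21e-05), among them the keratin genes KRT8 (3.25 ± 0.264) and KRT18 (1.97 ± 0.081). Genes of the ATF4 and unfolded protein response fell (2 up, 23 down and 3 not called of 28, 2 up and 23 down adjusted over the list alone, camera adjusted p = 9.57e-09). ASNS, the asparagine synthetase gene, stood at 212 against 770 CPM (-1.86 ± 0.056, adjusted p = 8.34e-16), and the serine synthesis gene PSAT1 fell (-1.18 ± 0.058). Over all tested genes 2998 rose and 3336 fell, 1264 and 311 at least 2-fold. Against the own pair 1427 and 552 changed at least 2-fold. Cholesterol genes were not called as a list (6 up, 0 down and 17 not called of 23, 5 up and 0 down adjusted over the list alone, camera adjusted p = 0.288). They rose against the own pair, 21 of 23 (adjusted p = 6.58e-18).

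ARID1B WT also turned on genes of the extracellular matrix. MMP2 rose to 227 ± 3.97 CPM (10.87 ± 0.177, adjusted p = 8.85e-20) and the elastin gene ELN from 0.147 ± 0.0895 to 441 ± 14.2 CPM (11.54 ± 0.2, adjusted p = 2.12e-19). LAMB1 rose to 160 ± 2.57 CPM (4.30 ± 0.066) and COL1A1 to 27.1 ± 2.66 CPM (5.19 ± 0.168). From no empty vector read, CACNG4 rose at least 497-fold, SEMA5B at least 438-fold, and the WNT inhibitor gene SOST at least 425-fold. In the same way DCX rose at least 359-fold, ISLR at least 279-fold and RUNX2 at least 239-fold. VSTM2L rose 2240 times (counting interval 621 to 18500) and COL16A1 2150 times (386 to 85100). PRLR fell to 1/404 of the empty vector level (72.4 to 16000 times). MAGEC2 (-5.22 ± 0.633), the WNT inhibitor gene DKK1 (-3.46 ± 0.216, adjusted p = 1.38e-10) and MAGEC1 (-3.37 ± 0.445) fell. GRB10 (-2.93 ± 0.272), LAMP3 (-2.81 ± 0.566), EMX2OS (-2.59 ± 0.352), INHBE (-2.52 ± 0.371) and KCNG1 (-2.52 ± 0.467) fell as well. Against the own pair LAMP3 (-1.18) and KCNG1 (-1.17) fell less.

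With ARID1B WT the matrix glycoprotein list rose (20 up, 3 down and 7 not called of 30, 20 up and 3 down adjusted over the list alone, camera adjusted p = 2.22e-33). Collagens rose (15 up, 1 down and 7 not called of 23, 16 up and 1 down adjusted over the list alone, camera adjusted p = 7.79e-14), and so did mesenchymal markers (7 up, 1 down and 4 not called of 12, 8 up and 1 down adjusted over the list alone, camera adjusted p = 1.68e-21). TEAD/YAP targets rose as well (16 up, 1 down and 4 not called of 21, 17 up and 1 down adjusted over the list alone, camera adjusted p = 2.61e-08). ATF4 genes fell (2 up, 17 down and 9 not called of 28, 3 up and 18 down adjusted over the list alone, camera adjusted p = 0.000106). ASNS fell by a smaller step than with ARID1A WT (-0.98 ± 0.054). Cell cycle genes fell (0 up, 19 down and 21 not called of 40, 0 up and 23 down adjusted over the list alone, camera adjusted p = 0.00169 and adjusted p = 0.77 with an estimated correlation). Against the own pair all 40 fell (adjusted p = 7.21e-07 with an estimated correlation). Against empty vector replicates 1 and 2 alone the cell cycle list leaned up and was not called (adjusted p = 0.908). In all 2736 genes rose and 3393 fell, 959 and 525 at least 2-fold. Against the own pair 1032 and 213 changed at least 2-fold. Without ARID1B WT replicate 2 the calls dropped from 6129 to 3957.

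The WT proteins shared more of their rises and falls than chance gives. Against own pairs, which share no control library, 815 genes rose at least 2-fold with both ARID1A WT and ARID1B WT where 103.6 were expected by chance. These were 57.1% of the rises with ARID1A WT and 79% of those with ARID1B WT. There 74 fell with both where 8.3 were expected, 13.4% and 34.7% of the falls. Of all calls against the 4 empty vector libraries 2146 rises and 2139 falls were shared, where 576.8 and 796 were expected if the contrasts were independent. They share their controls, which raises such an overlap, so these expected numbers are not a chance level. Log2 fold changes of ARID1A WT and ARID1B WT against own pairs correlated at 0.764 across 14220 genes (covariance 1.27). With all 4 empty vector libraries shared the correlation was 0.758 (covariance 1.254). Libraries simulated without any effect but with that shared control gave 0.326 (covariance 0.0168) and 0 genes called. The simulated empty vector libraries shared the same mean, without the split into pairs, so these values are not a chance level for these data.

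Set directly against ARID1B WT, ARID1A WT held more COL1A1 (1.72 ± 0.139, adjusted p = 1.15e-07) and more ITGA5, an integrin gene (1.11 ± 0.141, adjusted p = 2.96e-05). It also held more of the cadherin gene CDH2 (2.44 ± 0.468, adjusted p = 0.00175). It held less ELN (-3.28 ± 0.148, adjusted p = 3.52e-11), less MMP2 (-1.38 ± 0.118, adjusted p = 2.36e-07) and less SOST (-3.96 ± 0.336). Of the forebrain transcription factor gene FOXP2 it held no read (at least 176-fold lower). All fixed-list genes for cell division were more positive with ARID1A WT as a difference between own-pair responses, 40 of 40 (adjusted p = 5.79e-09 with an estimated correlation). Nearly all of them were higher in empty vector replicates 3 and 4 than in replicates 1 and 2. That difference between the control pairs enters the difference of own-pair responses in the same direction. The direct test gave 6 up, 0 down and 34 not called of 40, 6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0017 and adjusted p = 0.614 with an estimated correlation. ARID1A WT against ARID1B WT gave 1274 genes up and 648 down, 441 and 88 at least 2-fold. As a difference of own-pair responses there were 5910 calls, 566 up and 433 down at least 2-fold. That way ELN (-2.11 ± 1.209, adjusted p = 0.172), MMP2 (-1.94 ± 0.942, adjusted p = 0.105), FOXP2 (adjusted p = 0.0578) and SOST (adjusted p = 1) were not called, all 4 being near 0 in the controls. Leaving out a library moved the 1922 calls to 835 (ARID1A WT replicate 1), 874 (ARID1A WT replicate 2), 734 (ARID1B WT replicate 1) or 737 (ARID1B WT replicate 2).

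CBR kept part of the ARID1A WT response without a rise of MMP2 or LAMB1. MMP2 stood at 0.113 ± 0.0274 CPM with CBR, as with the empty vector (-0.03 ± 0.666, adjusted p = 0.975), and LAMB1 at 8.03 ± 0.0878 CPM (-0.01 ± 0.079, adjusted p = 0.908). ITGA5 rose as far as with WT (5.68 ± 0.159, adjusted p = 1.4e-15). COL1A1 rose by less (4.62 ± 0.173), ELN rose (7.25 ± 0.239), and ISLR rose at least 106-fold and COL16A1 283 times (50 to 11200). DKK1 (-3.68 ± 0.217), MAGEC2 (-3.44 ± 0.484) and MAGEC1 (-3.28 ± 0.428) fell. Interferon response genes rose (22 up, 2 down and 10 not called of 34, 23 up and 2 down adjusted over the list alone, camera adjusted p = 1.44e-08), with the antiviral gene IFI6 at 2.37 ± 0.155 and ISG15 at 1.56 ± 0.077. ATF4 genes fell (0 up, 22 down and 6 not called of 28, 0 up and 23 down adjusted over the list alone, camera adjusted p = 2.3e-09). CBR against the empty vector gave 3590 genes up and 3960 down, 1037 and 548 at least 2-fold.

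Against ARID1A WT, CBR lost MMP2 (-9.52 ± 0.243, adjusted p = 9e-16), LAMB1 (-5.35 ± 0.089, adjusted p = 5.47e-19) and COL12A1 (-8.14 ± 0.222). It held no read of CACNG4 (at least 194-fold lower) or CD44 (at least 142-fold lower). The sphingomyelinase-like gene SMPDL3B (2.76 ± 0.136, adjusted p = 7.55e-12), the chaperone pseudogene HSPA7 (2.54 ± 0.339) and the sterol exporter gene ABCG1 (2.43 ± 0.354) were higher. TEAD/YAP targets were lower (0 up, 13 down and 8 not called of 21, 0 up and 14 down adjusted over the list alone, camera adjusted p = 1.95e-08), with AXL at -2.90 ± 0.117. So were matrix glycoproteins (4 up, 17 down and 9 not called of 30, 4 up and 17 down adjusted over the list alone, camera adjusted p = 6.27e-09). Interferon genes were higher (19 up, 2 down and 13 not called of 34, 19 up and 2 down adjusted over the list alone, camera adjusted p = 0.000167), as were MHC class I genes (6 up, 0 down and 1 not called of 7, 6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0115). The transactivator gene NLRC5 (1.65 ± 0.245) and HLA-B (1.71 ± 0.302) led the last group. In all 3158 genes were higher and 3598 lower, 602 and 1027 at least 2-fold.

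delIDR1 raised matrix genes less than ARID1A WT and lowered cell cycle genes. MMP2 reached 3.23 ± 0.435 CPM (4.73 ± 0.294, adjusted p = 1.69e-10) and LAMB1 25.5 ± 1.65 CPM (1.65 ± 0.07). COL1A1 reached 14.0 ± 0.0978 CPM (4.24 ± 0.177) and ITGA5 33.3 ± 2.15 CPM (5.62 ± 0.159), and CD44 stayed at 0 reads. ISLR rose at least 69.8-fold, DCX at least 29.8-fold and COL16A1 330 times (58.5 to 13100). PRLR (-4.52 ± 0.485), ALDH1A2 (-4.01 ± 0.27) and MAGEC2 (-4.00 ± 0.519) fell. The replication helicase gene MCM7 fell (-0.69 ± 0.067, adjusted p = 8.17e-08) among cell cycle genes (0 up, 39 down and 1 not called of 40, 0 up and 39 down adjusted over the list alone, camera adjusted p = 1.06e-08 and adjusted p = 0.422 with an estimated correlation). Of the 40, 33 fell against the own pair (adjusted p = 0.000527 with an estimated correlation). In all 3188 genes rose and 3939 fell, 1076 and 301 at least 2-fold.

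Against ARID1A WT, delIDR1 had lower MMP2 (-4.76 ± 0.153, adjusted p = 3.36e-14), LAMB1 (-3.68 ± 0.08, adjusted p = 8.2e-17), COL12A1 (-5.47 ± 0.167) and AXL (-2.25 ± 0.111). It had no read of CD44 (at least 145-fold lower), CACNG4 lower 198 times (67.5 to 965) and the phosphatase gene PTPRO at -5.95 ± 0.34. ASNS (1.00 ± 0.06, adjusted p = 2.26e-10), SMPDL3B (2.12 ± 0.137), LAMP3 (2.07 ± 0.614) and KCNG1 (1.98 ± 0.496) were higher. As a list, ATF4 genes were higher than with WT (14 up, 4 down and 10 not called of 28, 15 up and 5 down adjusted over the list alone, camera adjusted p = 4.03e-06). Matrix glycoproteins were lower (4 up, 18 down and 8 not called of 30, 4 up and 18 down adjusted over the list alone, camera adjusted p = 1.8e-10). There were 2480 genes higher and 3234 lower, 407 and 684 at least 2-fold.

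The ARID-domain mutant DBDmut gave most of the ARID1A WT response at lower height. Among genes open to the naming rule, MMP2 fell furthest below WT. MMP2 reached 1.01 ± 0.00467 CPM (3.06 ± 0.39, adjusted p = 4.3e-06) against 87.4 with WT. LAMB1 reached 154 ± 9.56 (4.24 ± 0.066), COL1A1 17.3 ± 2.82 (4.54 ± 0.174) and CD44 3.11 ± 0.354 CPM (7.40 ± 0.42). DCX rose at least 148-fold, RUNX2 at least 97.3-fold and VSTM2L 672 times (185 to 5560). PRLR (-5.34 ± 0.543), MAGEC2 (-5.02 ± 0.603) and ALDH1A2 (-4.70 ± 0.293) fell. Matrix glycoproteins rose (22 up, 2 down and 6 not called of 30, 22 up and 2 down adjusted over the list alone, camera adjusted p = 9.1e-15). ATF4 genes fell (1 up, 19 down and 8 not called of 28, 1 up and 19 down adjusted over the list alone, camera adjusted p = 2.74e-09). DBDmut against the empty vector gave 2398 genes up and 2597 down, 894 and 241 at least 2-fold. There were 8392 calls against the own pair in place of 4995, 1098 up and 528 down at least 2-fold. Without DBDmut replicate 1 the calls were 3291, and without replicate 2 they were 3230.

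Between DBDmut and ARID1A WT, 142 genes were higher and 657 lower, 11 and 314 at least 2-fold. MMP2 (-6.43 ± 0.181, adjusted p = 1.09e-14), COL12A1 (-2.97 ± 0.132) and ITGA5 (-1.29 ± 0.142, adjusted p = 4.96e-06) were lower, as were the matrix receptor gene SUSD2 (-3.81 ± 0.208) and the neural adhesion gene L1CAM (-2.48 ± 0.17). SOST was lower 14.8 times (4.70 to 74.5). MAGEC1 (2.85 ± 0.617, adjusted p = 0.00681), HSD11B2 (0.88 ± 0.135) and DNALI1 (0.94 ± 0.265) were higher. Mesenchymal markers were lower (0 up, 7 down and 5 not called of 12, 0 up and 7 down adjusted over the list alone, camera adjusted p = 2.64e-30). So were matrix glycoproteins (0 up, 13 down and 17 not called of 30, 2 up and 16 down adjusted over the list alone, camera adjusted p = 2.19e-30) and collagens (0 up, 9 down and 14 not called of 23, 0 up and 10 down adjusted over the list alone, camera adjusted p = 4.32e-25). Fitted with the empty vector pairs apart, the same contrast gave 2711 calls, 1184 up and 1527 down, 30 and 417 at least 2-fold. Leaving out a library moved the 799 calls to 397 (DBDmut replicate 1), 451 (DBDmut replicate 2), 449 (WT replicate 1) or 412 (WT replicate 2).

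The DDX4 hybrid lowered amino acid stress genes further than ARID1A WT did and raised matrix genes less. ASNS fell to 109 ± 2.43 from 770 ± 35.3 CPM (-2.82 ± 0.06, adjusted p = 5.39e-17), and the glycine transporter gene SLC6A9 fell (-3.38 ± 0.197, adjusted p = 1.33e-10). The stress pseudokinase gene TRIB3 (-3.38 ± 0.495), INHBE (-4.26 ± 0.429) and the cystine transporter gene SLC7A11 (-3.14 ± 0.247) fell with them. ATF4 genes as a list fell (0 up, 26 down and 2 not called of 28, 0 up and 27 down adjusted over the list alone, camera adjusted p = 1.09e-62). COL1A1 rose (4.61 ± 0.171), as did ITGA5 (3.57 ± 0.178), LAMB1 by less (1.09 ± 0.071), RUNX2 at least 23.2-fold and ISLR at least 11.8-fold. TRIB3 fell by less against the own pair (-1.97 ± 0.071, adjusted p = 6.68e-18). Cholesterol genes fell (0 up, 10 down and 13 not called of 23, 0 up and 16 down adjusted over the list alone, camera adjusted p = 0.00216 and adjusted p = 0.666 with an estimated correlation). Against the own pair all 23 fell (adjusted p = 9.54e-08 with an estimated correlation). Against empty vector replicates 1 and 2 alone the cholesterol list leaned up and was not called (adjusted p = 0.822). In all 2805 genes rose and 2811 fell, 556 and 468 at least 2-fold, and 716 and 257 at least 2-fold against the own pair. The 5616 calls were 3060 without DDX4 replicate 1 and 3568 without replicate 2.

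Against ARID1A WT, the DDX4 hybrid had lower MMP2 (-6.76 ± 0.18, adjusted p = 1.37e-15), LAMB1 (-4.24 ± 0.082) and COL1A1 (-2.30 ± 0.141). It had no CD44 read (at least 176-fold lower), PTPRO lower 496 times (137 to 4100) and DCX lower 337 times (92.9 to 2790). MAGEC1 (4.45 ± 0.533) and MAGEC2 (3.98 ± 0.649) were higher, and DDX4 883 times higher (244 to 7300). Matrix glycoproteins were lower (5 up, 21 down and 4 not called of 30, 6 up and 21 down adjusted over the list alone, camera adjusted p = 9.51e-21), and ATF4 genes were too (0 up, 21 down and 7 not called of 28, 0 up and 23 down adjusted over the list alone, camera adjusted p = 5.01e-10). As a difference of own-pair responses PTPRO (adjusted p = 0.934) and DCX (adjusted p = 1) were not called, both being near 0 in the controls. There were 2391 genes higher and 2794 lower, 278 and 1178 at least 2-fold, and 726 and 949 at least 2-fold as a difference of own-pair responses.

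Libraries named AQGscram and 42YS raised few of the genes that ARID1A WT raised. ARID1A RNA with AQGscram was not above the empty vector (0.856-fold), so RNA does not bear out that the construct was expressed. Reads from an altered stretch may fail to map to ARID1A. With AQGscram COL1A1 reached 8.27 ± 0.610 CPM (3.48 ± 0.188, adjusted p = 5.33e-10). RUNX2 rose at least 4.92-fold, COL16A1 34.5 times (5.54 to 1420) and VSTM2L 25.4 times (6.47 to 219). With 42YS COL1A1 stayed at 0.856 ± 0.129 CPM (0.22 ± 0.288, adjusted p = 0.595). RUNX2 rose at least 3.78-fold, COL16A1 24.3 times (3.74 to 1020) and C15orf52 by 3.56 ± 0.384. GDF15 fell with AQGscram (-2.78 ± 0.673) and with 42YS (-3.15 ± 0.694). The netrin receptor gene UNC5B (-2.63 ± 0.631) fell with AQGscram, and LAMP3 (-3.38 ± 0.587) and TIMP3 (-2.99 ± 0.759) fell with 42YS. Of these GDF15, UNC5B and LAMP3 were already lower in empty vector replicates 3 and 4 than in replicates 1 and 2. Against replicates 3 and 4 alone GDF15 (-0.47) and UNC5B (-0.49) fell less with AQGscram, as GDF15 (-0.84) and LAMP3 (-1.75) did with 42YS. TIMP3 was not called against replicates 3 and 4 alone (-0.31). ATF4 genes fell with AQGscram (0 up, 14 down and 14 not called of 28, 0 up and 16 down adjusted over the list alone, camera adjusted p = 9.38e-05), and they fell with 42YS (1 up, 17 down and 10 not called of 28, 1 up and 18 down adjusted over the list alone, camera adjusted p = 1.77e-14). Both constructs lie in set 3, which holds no empty vector library, so a difference of the set could give this fall. AQGscram gave 1552 genes up and 1955 down, 299 and 255 at least 2-fold. 42YS gave 2241 up and 2559 down, 244 and 412 at least 2-fold. The AQGscram replicates differed by a chi-square per degree of freedom of 30.4, against 1.18 to 4.97 for the other pairs of replicates within a set. Without AQGscram replicate 2 its 3507 calls were 2242. A fit of AQGscram and the empty vector alone called 3 genes, COL1A1 (3.46) not among them. The 4800 calls of 42YS were 2413 without replicate 1 and 2589 without replicate 2.

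Both constructs stood far below ARID1A WT for matrix genes. AQGscram had lower LAMB1 (-4.87 ± 0.086, adjusted p = 1.66e-18) and LRRC15 (-8.75 ± 0.259), no read of the laminin gene LAMB3 (at least 151-fold lower) and DCX lower 583 times (104 to 23100). MAGEC2 (4.46 ± 0.629), MAGEC1 (4.26 ± 0.542) and PRLR (3.52 ± 0.558) were higher. 42YS had lower LAMB1 (-4.64 ± 0.084, adjusted p = 3.05e-18), no CACNG4 read (at least 210-fold lower), ALPK2 lower 495 times (137 to 4090) and PTPRO lower 434 times (120 to 3590). PRLR (3.90 ± 0.545), MAGEC2 (3.89 ± 0.659) and MAGEC1 (3.66 ± 0.567) were higher. Matrix glycoproteins were lower with AQGscram (4 up, 21 down and 5 not called of 30, 4 up and 23 down adjusted over the list alone, camera adjusted p = 2.62e-25). They were lower with 42YS, too (3 up, 22 down and 5 not called of 30, 3 up and 22 down adjusted over the list alone, camera adjusted p = 5.94e-23). Against WT, AQGscram had 2810 genes higher and 3063 lower, 295 and 1336 at least 2-fold. 42YS had 3489 higher and 3598 lower, 465 and 1577 at least 2-fold. Between the 2 constructs, in a contrast chosen after the data were seen, 42YS had less COL1A1 (-3.27 ± 0.214, adjusted p = 2e-11), AXL (-1.26 ± 0.129) and ASNS (-0.78 ± 0.044). It had 113 genes at least 2-fold higher and 259 lower.

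ARID1B M2 kept most of the ARID1B WT matrix response and lowered ATF4 genes further. ELN reached 333 CPM (11.14 ± 0.201, adjusted p = 4.49e-19) and MMP2 138 ± 2.44 CPM (10.15 ± 0.18, adjusted p = 4e-19). SOST rose at least 254-fold and VSTM2L 2730 times (755 to 22600). ASNS (-3.07 ± 0.061, adjusted p = 1.62e-18), INHBE (-4.55 ± 0.452) and AKNA (-3.75 ± 0.249) fell. Matrix glycoproteins rose (22 up, 4 down and 4 not called of 30, 22 up and 4 down adjusted over the list alone, camera adjusted p = 1.7e-25). ATF4 genes fell (1 up, 24 down and 3 not called of 28, 1 up and 24 down adjusted over the list alone, camera adjusted p = 1.67e-24). M2 against the empty vector gave 3148 genes up and 3574 down, 1004 and 674 at least 2-fold, and 1118 and 351 at least 2-fold against the own pair.

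Set against ARID1B WT, M2 lowered ASNS (-2.09 ± 0.062, adjusted p = 3.05e-14) and the glutathione-degrading enzyme gene CHAC1 (-2.06 ± 0.122). ATF4 genes were lower as a list (1 up, 19 down and 8 not called of 28, 1 up and 24 down adjusted over the list alone, camera adjusted p = 1.88e-46). CD44 (-5.18 ± 0.272, adjusted p = 2.7e-09), the decoy receptor gene IL13RA2 (-3.33 ± 0.226), PTPRO (-3.12 ± 0.243) and the proteoglycan gene VCAN (-3.55 ± 0.464) were lower. DKK1 (4.14 ± 0.223, adjusted p = 2.61e-10), MAGEC2 (5.33 ± 0.661) and PRLR (146 times, 25.8 to 5790) were higher. Cell cycle genes were higher (16 up, 0 down and 24 not called of 40, 24 up and 0 down adjusted over the list alone, camera adjusted p = 7.29e-11 and adjusted p = 0.465 with an estimated correlation). With the empty vector pairs fitted apart 37 of 40 were (adjusted p = 2.13e-07 with an estimated correlation). Cholesterol genes were lower (0 up, 5 down and 18 not called of 23, 0 up and 8 down adjusted over the list alone, camera adjusted p = 6.58e-06 and adjusted p = 0.528 with an estimated correlation). In that other fit 22 of 23 were (adjusted p = 2.13e-07 with an estimated correlation). There were 1181 genes higher and 854 lower, 165 and 179 at least 2-fold, and the other fit gave 4893 calls. Leaving out a library moved the 2035 calls to 975 (M2 replicate 1), 1016 (M2 replicate 2), 978 (WT replicate 1) or 935 (WT replicate 2).

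MMP2, ELN and LAMB1 stood in falling order with the ARID1B deletions A457_G461del, Block13del and Block9del. MMP2 reached 24.7 ± 1.26, 9.16 ± 0.420 and 2.78 ± 0.427 CPM (log2 fold changes against the empty vector 7.67 ± 0.206, 6.24 ± 0.24 and 4.51 ± 0.301). ELN reached 20.5 ± 1.32, 9.03 ± 2.60 and 0.789 ± 0.255 CPM, and LAMB1 54.2 ± 1.21, 31.1 ± 0.442 and 20.3 ± 0.534 CPM. DCX rose at least 175-fold, 57.5-fold and 39.7-fold. VSTM2L rose 696 times (192 to 5760), 251 times (68.7 to 2080) and 53.2 times (14.2 to 448). SEMA5B rose at least 65.6-fold with A457_G461del, and FOXP2 216 times (38.0 to 8580) with Block13del and 66.7 times (11.3 to 2700) with Block9del. ASNS fell in all 3 (-2.83 ± 0.06, adjusted p = 1.25e-17, -2.55 ± 0.059, adjusted p = 1.28e-16 and -2.51 ± 0.059, adjusted p = 3.46e-16). INHBE fell further (-5.98 ± 0.531, -4.78 ± 0.475 and -4.62 ± 0.455). Since set 3 holds no empty vector library, these common falls cannot be told from a difference of the set. AKNA (-3.82 ± 0.25) and SLC6A9 (-3.70 ± 0.204) fell with A457_G461del. LAMP3 (-3.73 ± 0.617) and GDF15 (-3.72 ± 0.736) fell with Block13del, and GDF15 (-3.75 ± 0.731) and SLC6A9 (-3.37 ± 0.199) with Block9del. Against empty vector replicates 3 and 4 alone GDF15 fell less with Block13del (-1.41) and Block9del (-1.43), and so did LAMP3 with Block13del (-2.09).

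ATF4 genes fell with A457_G461del (0 up, 25 down and 3 not called of 28, 0 up and 27 down adjusted over the list alone, camera adjusted p = 9.15e-47) and Block13del (0 up, 27 down and 1 not called of 28, 0 up and 27 down adjusted over the list alone, camera adjusted p = 4.25e-52). They fell with Block9del (0 up, 26 down and 2 not called of 28, 0 up and 27 down adjusted over the list alone, camera adjusted p = 6.32e-51). Matrix glycoproteins rose with A457_G461del (16 up, 4 down and 10 not called of 30, 16 up and 5 down adjusted over the list alone, camera adjusted p = 2e-10) and Block13del (8 up, 4 down and 18 not called of 30, 8 up and 4 down adjusted over the list alone, camera adjusted p = 0.000293). With Block9del that list was at 6 up, 6 down and 18 not called of 30, 6 up and 6 down adjusted over the list alone, camera adjusted p = 0.356. Against empty vector replicates 1 and 2 alone the matrix list was not called with Block13del (adjusted p = 0.213). Against the empty vector, A457_G461del gave 2718 genes up and 2827 down (577 and 537 at least 2-fold). The counts were 2712 and 2875 (333 and 547) with Block13del and 2535 and 3016 (216 and 623) with Block9del. Without replicate 1 or 2 of A457_G461del its 5545 calls were 3327 and 3303. Without Block13del replicate 1 its 5587 were 3037, and without replicate 1 or 2 of Block9del its 5551 were 3049 and 3544.

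Against ARID1B WT, CD44 was lower with A457_G461del (-4.60 ± 0.256, adjusted p = 2.23e-09), Block13del (653 times, 117 to 25800) and Block9del (369 times, 102 to 3060). ELN was lower with all 3 (-4.42 ± 0.157, -5.60 ± 0.17 and -9.10 ± 0.219, adjusted p = 6e-16). IL13RA2 was lower with A457_G461del (-3.95 ± 0.238) and Block13del (-5.67 ± 0.287), and SOST had no read with Block9del (at least 267-fold lower). PRLR was higher 105 times (18.6 to 4190), 208 times (37.0 to 8250) and 175 times (31.1 to 6950). MAGEC2 was higher by 4.41 ± 0.713, 4.97 ± 0.684 and 4.89 ± 0.684. Matrix glycoproteins were lower with A457_G461del (2 up, 19 down and 9 not called of 30, 3 up and 21 down adjusted over the list alone, camera adjusted p = 2.39e-24) and Block13del (5 up, 21 down and 4 not called of 30, 5 up and 22 down adjusted over the list alone, camera adjusted p = 7.54e-22). The same held with Block9del (5 up, 22 down and 3 not called of 30, 5 up and 23 down adjusted over the list alone, camera adjusted p = 3.08e-23). A457_G461del had 2071 genes higher and 2145 lower (221 and 605 at least 2-fold), Block13del 3040 and 3129 (427 and 1000) and Block9del 3233 and 3466 (519 and 1179). The 4216 calls of A457_G461del were 2592 without ARID1B WT replicate 2, 2769 without A457_G461del replicate 1 and 2682 without its replicate 2.

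Contrasts within set 3, chosen after the data were seen, put A457_G461del above Block9del for MMP2 (3.15 ± 0.118, adjusted p = 5.68e-17), ELN (4.67 ± 0.193, adjusted p = 3.93e-16) and LAMB1 (1.42 ± 0.067, adjusted p = 7.03e-15). At least 2-fold apart were 477 genes, 20 of them lower. Block13del stood above Block9del for MMP2 (1.73 ± 0.143, adjusted p = 9.97e-09) and ELN (3.52 ± 0.229, adjusted p = 8.09e-11) but not for COL1A1 (0.33 ± 0.314, adjusted p = 0.785). It had 53 genes at least 2-fold higher and 0 lower, and 10 genes lower at any fold. A457_G461del stood above Block13del for MMP2 (1.43 ± 0.097, adjusted p = 3.41e-11), with 187 genes at least 2-fold higher and 13 lower.

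Among the ARID1A mutants, the genes that ARID1A WT raised moved least with 42YS and most with DBDmut. Over the 2998 genes that rose with ARID1A WT the median log2 fold change against the empty vector was 0.79 with WT, 0.54 with DBDmut, 0.47 with delIDR1, 0.41 with CBR and 0.33 with DDX4. It was 0.11 with AQGscram and 0.02 with 42YS. Of the 1264 that rose at least 2-fold, a direct test against WT found 37.1% lower with DBDmut, 61.0% with delIDR1, 69.5% with CBR, 79.1% with DDX4, 86.3% with AQGscram and 91.9% with 42YS. These genes, like the other gene sets here, were chosen in the WT libraries that the mutants were then set against. That choice favours weaker responses with the mutants. Against own pairs, over 1427 genes, the order of the shares changed, with 53.7% lower with DBDmut, 54.9% with DDX4, 69.6% with delIDR1 and 74.6% with CBR. The DDX4 share came from a difference of own-pair responses across sets, the others from contrasts within set 1. Own-pair medians over these genes kept the order: 2.10 with WT, 1.53 with DBDmut, 1.30 with delIDR1, 0.995 with CBR and 0.742 with DDX4. Over the 3336 genes that fell with ARID1A WT the medians were -0.44, -0.33, -0.29, -0.27, -0.23, -0.13 and -0.09 in the order of the rising medians. Of the 311 that fell at least 2-fold, 7.1% fell less than with WT in the direct test with DBDmut, 52.1% with delIDR1, 48.6% with CBR, 43.1% with DDX4, 57.6% with AQGscram and 60.1% with 42YS. Over the 552 that fell at least 2-fold against the own pair, these shares were 12.1% with DBDmut, 67.9% with delIDR1, 64.1% with CBR and 69.2% with DDX4. Over these 552 the DDX4 hybrid stood at -0.07 against its own pair and at -0.73 against all 4 empty vector libraries. The 2736 genes that rose with ARID1B WT had medians of 0.64 with WT, 0.62 with M2, 0.35 with A457_G461del, 0.16 with Block13del and 0.03 with Block9del. The 3393 that fell had -0.47, -0.40, -0.26, -0.15 and -0.11. Of the 959 that rose at least 2-fold, 19.0% were lower than WT with M2, 65.7% with A457_G461del, 85.0% with Block13del and 90% with Block9del. Of the same 959, 11.1% were higher with M2 than with WT. Against the own pair, M2 was lower in 319 of 1032 genes (30.9%) and higher in 203. The medians there were 2.47 with M2 and 2.64 with WT. Of the 525 that fell at least 2-fold, 11.8% with M2, 14.9% with A457_G461del, 22.7% with Block13del and 25.1% with Block9del fell less than with WT. The median of these genes around the empty vector mean was 0.70 and 0.76 in empty vector replicates 1 and 2 and -0.77 and -0.75 in replicates 3 and 4, so the pairs parted on them. Of the 213 that fell at least 2-fold against the own pair 41.8% fell less with M2. With genes chosen against a pair of empty vector libraries and fold changes taken against the other pair, the medians over rising genes, averaged over the ways to split the libraries, were 0.65 with ARID1A WT (0.38 to 0.79 over the splits), 0.44 with DBDmut (0.24 to 0.55) and 0.36 with delIDR1 (0.08 to 0.47). They were 0.32 with CBR (0.05 to 0.42), 0.25 with DDX4 (0.07 to 0.32), 0.05 with AQGscram (-0.12 to 0.10) and -0.02 with 42YS (-0.15 to 0.02). For ARID1B they were 0.53 with WT (0.21 to 0.64), 0.52 with M2 (0.22 to 0.62), 0.28 with A457_G461del (0.10 to 0.35), 0.10 with Block13del (-0.01 to 0.15) and -0.01 with Block9del (-0.12 to 0.03). The same exchange brought falling genes to means of -0.07 with AQGscram (-0.14 to 0.13), -0.03 with 42YS (-0.09 to 0.16), -0.07 with Block13del (-0.17 to 0.15) and -0.04 with Block9del (-0.13 to 0.19). Libraries simulated without an effect gave a median of 0.05 over 2998 rising genes, chosen and measured against the same controls. That value goes with the first medians over genes that rose with ARID1A WT, not with the exchanged ones. The simulation left out the split of the empty vector into pairs.

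**Figure D2:**
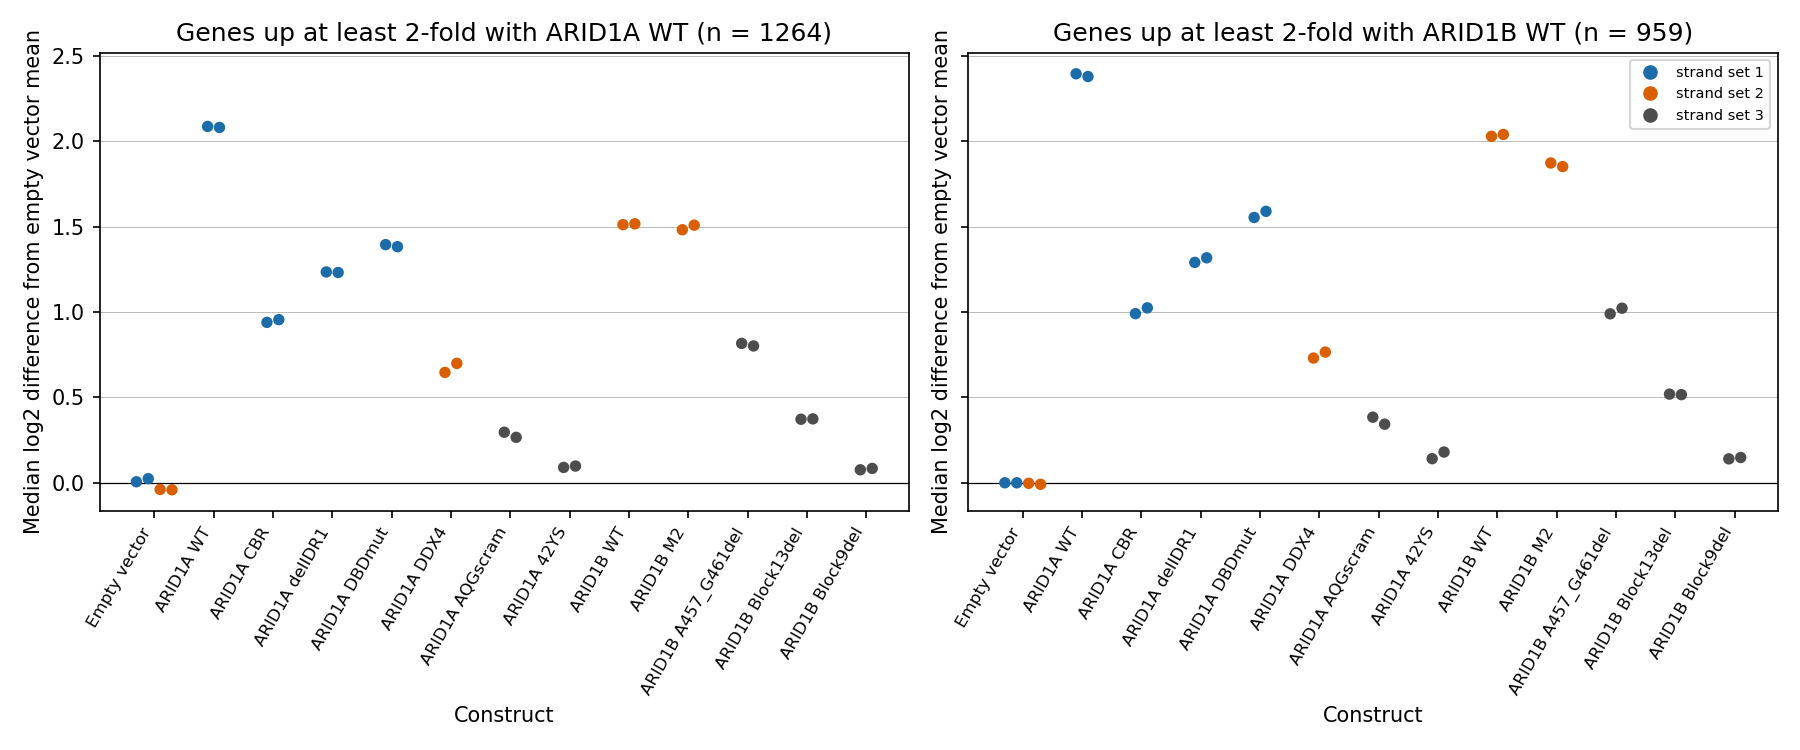
Median log2 difference from the empty vector mean in each library (points) over the genes that rose with ARID1A WT at least 2-fold (left, 1264 genes) or with ARID1B WT at least 2-fold (right, 959 genes). The fitted median over the ARID1A WT genes was 2.33 with WT and 0.10 with 42YS.

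Few markers of other cell types had enough reads to be tested: 2 of 10 endothelial, 1 of 14 immune and 1 of 14 germline markers. Some of those tested rose with the WT proteins. Of the endothelial markers EGFL7 rose with ARID1A WT (0.51 ± 0.083, adjusted p = 4.25e-05) and ARID1B WT (0.39 ± 0.083). Of the immune markers the lysosomal gene CD68 rose with both (2.96 ± 0.161, adjusted p = 1.03e-11 and 2.77 ± 0.163). The germline marker MAGEA4 rose with ARID1A WT (0.23 ± 0.076, adjusted p = 0.0181), but not against empty vector replicates 3 and 4 alone (0.10).

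**Figure D3:**
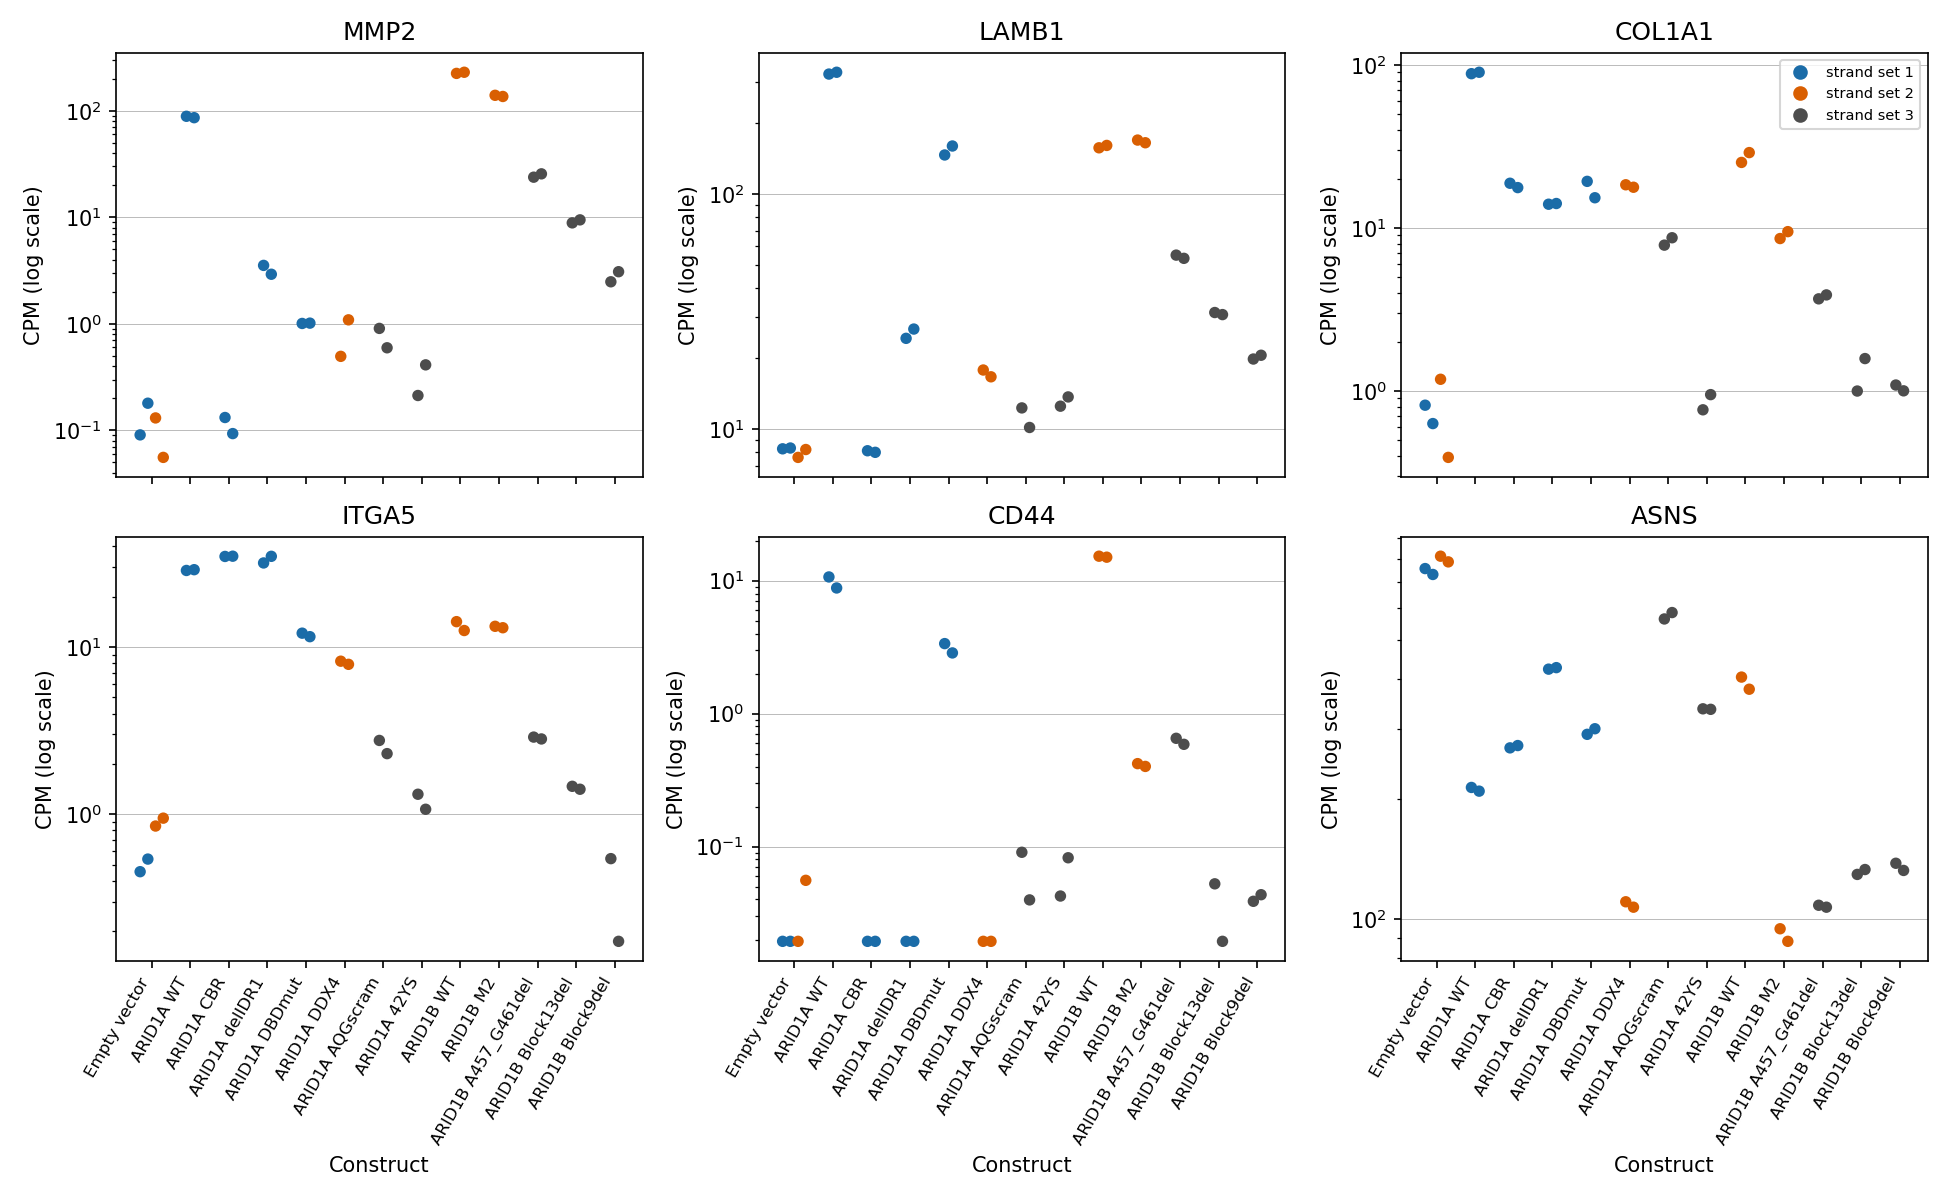
CPM of MMP2, LAMB1, COL1A1, ITGA5, CD44 and ASNS in each library (points) of the 13 groups, on a log axis with 0 drawn at the lower edge. MMP2 averaged 0.114 CPM with the empty vector and 227 CPM with ARID1B WT.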

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

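The strand and GC content tests over all genes of the empty vector pairs were written before their results were seen, and all other tests in this part, those against own pairs included, were chosen after.

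The responses to ARID1A WT and ARID1B WT, each against its own empty vector pair, differed at least 2-fold for 999 genes, a difference between groups that the interaction test called. Of these, 566 were more positive with ARID1A WT and 433 with ARID1B WT. The responses also differed in 3 gene lists: cell cycle and DNA replication genes (median log2 difference 1.011), cholesterol genes (0.859) and p53 targets (-0.63). The same lists parted the empty vector pairs, replicates 3 and 4 against replicates 1 and 2, by medians of 0.71, 1.03 and -0.83. Set directly against each other, ARID1A WT and ARID1B WT differed by medians of 0.25, -0.20 and 0.22.

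The empty vector pairs differed at least 2-fold in 1459 genes, among them CDKN1A and GDF15. Of these genes 69.5% (67.1 to 71.9, 1014 of 1459) stayed called and 2-fold apart with strand ignored, which argues against reads on the wrong strand as the cause of the whole difference, and 89% (87.2 to 90.6, 1173 of 1318) stayed 2-fold apart after a trend on GC content and transcript length was removed, which argues against that bias. Strand is a candidate explanation for 373 genes read mostly from the gene's own strand in replicates 3 and 4, of which 45 (12.1%, 8.9 to 15.8) stayed apart. For genes chosen so, the added reads of the gene's own strand dilute any difference. This share therefore cannot tell wrong-strand reads from a true difference. For the genes outside these 373, a library batch and a different state of the cells cannot be told apart, because each pair lies in its own strand set. The design gives the pairs no biological difference, so none was tested.

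All 4 ARID1A constructs of set 1 raised 425 genes and lowered 107 genes at least 2-fold against empty vector replicates 1 and 2, by median log2 changes of 2.592 and 2.028. For the lowered genes, empty vector replicates 3 and 4 were already lower by 68.9% of that median (59.8 to 84.0), and the DDX4 hybrid against its own pair moved -1.6% of it (-14.2 to 4.8). With genes chosen against 1 of replicates 1 and 2 and measured against the other, replicates 3 and 4 were lower by 69.2% and 73.6%, so a candidate explanation for these falls is that replicates 1 and 2 stand apart, while a common ARID1A effect stays open, since the control pair of the hybrid was itself lower. For the raised genes, replicates 3 and 4 moved 5.7% (0 to 13.4), and 6.7% (0 to 13.9) and 2.4% (0 to 8.7) with choice and measurement apart, which argues against the controls as the cause, since that needs at least 50%, though not against a small part, as only the last interval is clear of 10%. The DDX4 hybrid moved 51.8% (46.2 to 57.1), an interval that spans the 50% set for a common ARID1A effect, which stays open.

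The WT responses were weaker in most mutants. In AQGscram and 42YS, the weakest ARID1A responders, the highest library held 0.534 times the ARID1A RNA of the lowest ARID1A WT library. A low RNA level is thus a candidate explanation there, although 42YS held more of it than AQGscram. Nor can it be set aside for DBDmut, delIDR1 and the DDX4 hybrid. Their highest libraries held 694, 597 and 528 CPM of ARID1A, against 702 in the lowest ARID1A WT library. Truncated, hybrid or altered constructs may yield fewer ARID1A reads per transcript than WT. CPM may thus understate the level of delIDR1, the hybrid, AQGscram and 42YS. A457_G461del and Block9del, both of set 3, differed by a median of 1.122 (1.039 to 1.203) over the genes raised at least 2-fold by ARID1B WT. Over these genes, medians of single libraries against the empty vector mean were 0.989 and 1.022 with A457_G461del and 0.14 and 0.148 with Block9del. This difference argues against the missing control of their set as the only cause. Transgene RNA could not be set aside for the 3 deletions of set 3, whose responses ranked as their ARID1B RNA did, while 2 of the 5 ARID1B constructs, WT and M2, ranked the other way round. For CBR a lower RNA level is excluded, since its lowest library held 1.31 times the ARID1A RNA of the highest ARID1A WT library. A blot of CBR protein, not analysed here, would tell a lower protein level from a weaker function.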

How the results depend on the processing

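Of the tests in this part, those against own pairs (within strand sets), with strand ignored and with replicates swapped within a set were chosen after the result was seen, and the others were fixed before the data were examined. No count of genes called, over 23 contrasts, moved by more than 1.5 times with DESeq2, with RLE size factors, with no low-count filter, with the stricter filter or with strand ignored. None of the 12 against the empty vector did with replicates 3 and 4 as the only control. Of 3682 recomputed values of 259 gene results, 3599 kept direction and side of the threshold, 67 lost their call, 7 gained one and 9 changed direction. For 56 gene list results the figures were 299, 16, 7 and 4 of 326. Some genes were not tested under the stricter filter, in fits of 2 groups or with strand ignored and gave no value there. The libraries share only a replicate number: over 78 pairs of groups the residuals of equal numbers correlated at -0.13 to 0.12 (median 0.002). As a block the number takes up the split of the empty vector into replicates 1 and 2 against 3 and 4, since no construct has replicates 3 and 4.

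With the replicate block the counts that moved were 8806 with DDX4, 8523 with AQGscram, 8634 with 42YS, 8330 with DBDmut, 8991 with A457_G461del, 9007 with Block13del and 9057 with Block9del. Between constructs they were 7818 for DDX4 against ARID1A WT, 2663 for DBDmut against ARID1A WT, 4836 for M2 against ARID1B WT, 6936 for A457_G461del against ARID1B WT and 4926 for ARID1A WT against ARID1B WT. With empty vector replicates 1 and 2 as the only control they were 8796 with DDX4, 8502 with AQGscram, 8620 with 42YS, 8306 with DBDmut, 8974 with A457_G461del, 8996 with Block13del and 9031 with Block9del. Within strand sets they were 8392 with DBDmut. Between constructs they were 2711 for DBDmut against ARID1A WT, 4893 for M2 against ARID1B WT and 5910 for ARID1A WT against ARID1B WT. In fits of only the 2 groups compared, which hold fewer samples, they were 2748 with ARID1A WT, 3666 with CBR, 2839 with delIDR1, 1426 with DDX4, 3 with AQGscram, 722 with 42YS, 1342 with DBDmut, 2140 with ARID1B WT, 2655 with M2, 1587 with A457_G461del, 788 with Block13del and 838 with Block9del. Between constructs they were 9311 for delIDR1 against ARID1A WT, 8588 for DDX4 against ARID1A WT, 2723 for DBDmut against ARID1A WT, 6573 for M2 against ARID1B WT, 8200 for A457_G461del against ARID1B WT and 6326 for ARID1A WT against ARID1B WT. The cause of the moves was not tested, except that fits with the empty vector pairs apart had a common biological coefficient of variation of 0.0426 in place of 0.0969.

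Leaving out 1 library at a time gave 3060 to 6378 with DDX4, 2242 to 5159 with AQGscram, 2413 to 5830 with 42YS, 3230 to 5518 with DBDmut, 3957 to 6791 with ARID1B WT, 3303 to 6438 with A457_G461del, 3037 to 6613 with Block13del and 3049 to 6683 with Block9del. Between constructs it gave 397 to 451 for DBDmut against ARID1A WT, 935 to 1016 for M2 against ARID1B WT, 2592 to 2841 for A457_G461del against ARID1B WT and 734 to 874 for ARID1A WT against ARID1B WT. The other 11 counts stayed within 1.5 times. A group left with 1 library is assumed to vary like the others, since edgeR pools the spread.

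Median responses on the log2 scale, with genes chosen against a pair of empty vector libraries and folds taken against the other, averaged over the splits, were over genes up with ARID1A WT 0.649 with ARID1A WT, 0.319 with CBR, 0.36 with delIDR1, 0.252 with DDX4, 0.051 with AQGscram, -0.02 with 42YS and 0.442 with DBDmut. Over genes down with ARID1A WT they were -0.365 with ARID1A WT, -0.208 with CBR, -0.229 with delIDR1, -0.158 with DDX4, -0.069 with AQGscram, -0.025 with 42YS and -0.26 with DBDmut. Over genes up with ARID1B WT they were 0.533 with ARID1B WT, 0.521 with M2, 0.281 with A457_G461del, 0.099 with Block13del and -0.006 with Block9del. Over genes down with ARID1B WT they were -0.38 with ARID1B WT, -0.309 with M2, -0.177 with A457_G461del, -0.072 with Block13del and -0.038 with Block9del. The mean 42YS and Block9del responses over rising genes changed sign there. In single splits so did those of AQGscram (to -0.119) and Block13del (-0.01) over rising genes, and over falling genes those of CBR (0.034), DDX4 (0.037), AQGscram (0.126), 42YS (0.159), A457_G461del (0.017), Block13del (0.147) and Block9del (0.193). With a single empty vector library of the own set in each role they were over genes up with ARID1A WT 0.653 with ARID1A WT, 0.296 with CBR, 0.311 with delIDR1 and 0.569 with DBDmut. Over genes down with ARID1A WT they were -0.463 with ARID1A WT, -0.247 with CBR, -0.265 with delIDR1 and -0.399 with DBDmut. Over genes up with ARID1B WT they were 0.595 with ARID1B WT and 0.613 with M2. Over genes down with ARID1B WT they were -0.428 with ARID1B WT and -0.318 with M2. A gene chosen and measured against the same libraries carries their error into both steps. Simulated libraries without an effect, whose controls held no split into pairs, gave a median of 0.053. The exchanges concerned empty vector libraries only. The WT libraries served for both choice and measurement, which favours WT over the mutants.

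The cholesterol list with DDX4 changed from down to up, uncalled, with the replicate block (adjusted p = 0.847) and with empty vector replicates 1 and 2 alone (adjusted p = 0.822), and the cell cycle list with ARID1B WT did so too (adjusted p = 0.906 and adjusted p = 0.908). SMARCA4 turned from a fall to a rise with ARID1A WT (0.16 with the block, 0.162 with replicates 1 and 2 alone, 0.16 within sets) and with ARID1B WT (0.141 and 0.14 in the first pair of these). With strand ignored SNX22 with M2 turned to 0.029 and ATP6V1C2 in ARID1A WT against ARID1B WT to -0.016. Within sets the latter contrast gave -0.156 for ATP6V1C2 and -0.567 for ZACN. The cause was not tested, beyond the strand share for SNX22 and ATP6V1C2. Small changes were missed more often: of genes changed 1.5-fold in simulated data 44.7 to 63.3% were called over 4 contrasts, and of those changed 4-fold 89.6 to 96.0%, with 4.29 to 8.05% of calls false.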

Other observations

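The tests in this part followed the plan, except those against own pairs and of subunits without ARID1A and ARID1B, which were chosen after the result was seen.

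RNA of most other subunits of the canonical BAF complex moved little beside the transgenes. The list of subunit genes, ARID1A and ARID1B included, stood with ARID1A WT at 5 up, 4 down and 12 not called of 21, 5 up and 4 down adjusted over the list alone, camera adjusted p = 0.703. With ARID1B WT it stood at 4 up, 2 down and 15 not called of 21, 4 up and 2 down adjusted over the list alone, camera adjusted p = 0.0153 and adjusted p = 0.342 with an estimated correlation. Without ARID1A and ARID1B, 4 of 19 subunit genes rose and 3 fell with ARID1A WT (camera adjusted p = 0.837), and 3 rose and 1 fell with ARID1B WT (camera adjusted p = 0.607), the same counts as adjusted over the list alone. The subunit gene BCL7A rose with ARID1A WT from 46.7 ± 1.92 to 97.5 ± 1.80 CPM (1.06 ± 0.054, adjusted p = 3.49e-12) and with ARID1B WT (0.53 ± 0.055, adjusted p = 2.53e-07). The PHD finger subunit gene DPF3 rose from 0.145 ± 0.0362 CPM with both (1.76 ± 0.556 and 2.32 ± 0.509). The actin-related subunit gene ACTL6A fell with both (-0.42 ± 0.062 and -0.27 ± 0.062). SMARCA2, an ATPase gene of the complex, fell with ARID1A WT (-0.34 ± 0.065, adjusted p = 0.000283). It fell with A457_G461del (-0.57 ± 0.065), Block13del (-0.61 ± 0.065) and Block9del (-0.58 ± 0.065) but was not called with ARID1B WT (-0.05 ± 0.063, adjusted p = 0.551). The 3 deletions lie in set 3, which holds no empty vector library, so their common fall cannot be told from a difference of the set. SMARCA4, the other ATPase gene, was not called with ARID1A WT (-0.06 ± 0.094, adjusted p = 0.631) or ARID1B WT (-0.08 ± 0.094, adjusted p = 0.515). Against own pairs SMARCA4 rose with ARID1A WT (0.16 ± 0.042) and fell with ARID1B WT (-0.27 ± 0.042).

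Genes of axon guidance and synaptic adhesion rose beside the matrix genes. With ARID1A WT they stood at 12 up, 0 down and 7 not called of 19, 12 up and 0 down adjusted over the list alone, camera adjusted p = 8.54e-07. With ARID1B WT they stood at 12 up, 2 down and 5 not called of 19, 12 up and 3 down adjusted over the list alone, camera adjusted p = 2.98e-06. The semaphorin gene SEMA3F rose with ARID1A WT (2.88 ± 0.054, adjusted p = 9.8e-19) and with ARID1B WT (2.37 ± 0.054, adjusted p = 1.53e-17). So did the semaphorin receptor gene PLXNA2 (1.47 ± 0.138 and 2.41 ± 0.13). Outside this list the neural adhesion gene L1CAM rose with ARID1A WT (5.68 ± 0.178). Against all empty vector libraries, cytosolic ribosomal protein genes with CBR stood at 0 up, 57 down and 1 not called of 58, 0 up and 57 down adjusted over the list alone, camera adjusted p = 1.4e-09 and adjusted p = 0.501 with an estimated correlation. Nearly all of these genes were lower in the empty vector pair of set 1, the set of CBR, than in the other pair. That difference between the control pairs enters this fall, which therefore cannot be read as an effect of CBR alone.

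Reads that named no gene (multimapping, no feature, ambiguous or unmapped) were 31.3 to 36.3% of all listed reads in set 1, 21.6 to 24.1% in set 2 and 27.5 to 30.2% in set 3. Genes with at least 1 read numbered 16165 to 17490, 15043 to 16703 and 15768 to 16353 in the same order.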
